A study of Homo sapiens with 4 samples.

How the data were processed

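SMC1 HiChIP libraries of GM12878 cells were analysed, 4 in all, with 1 library in each of the groups DMSO, APH, H2O and HU. Groups were taken from the treatment given in the labels. The sample titles name another lymphoblastoid line, while the source, the cell line field and the library names say GM12878, which is used here. Per the labels' protocols, chromatin was fixed with formaldehyde and a longer cross-linker and processed with a commercial Hi-C kit, and SMC1 was precipitated with an antibody. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17, peaks were called with MACS3 3.0.1, and the genome build was hg38. The aligner, the loop caller and its filters are not given in the sources used here.

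The authors deposited 1 list of called loops per library, with no header, so the meaning of each column was read from its values. The deposited contact counts are whole numbers of at least 12 per pair of 5 kb bins and were not normalized. A deposited column that is not whole is taken as the count expected by the caller's background model, since the observed count is at least 2 times as high for every loop. The deposited column taken as the adjusted p-value (false discovery rate) lies below 0.01 for every loop. Deposited columns with a cluster score and a summit mark were not used. The lists hold only called loops, within a chromosome and 10 to 1000 kb apart, so the total read depth is unknown, an unlisted pair is not a 0, and a sum over a list moves with how much was called. The loops listed in all 4 libraries hold 66.8% of the listed counts in DMSO, 51.4% in APH, 56.6% in H2O and 58.5% in HU. Over these loops the totals were 300320 in DMSO, 376948 in APH, 325634 in H2O and 322048 in HU.

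Ratios were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. Counts of loops listed in all 4 libraries were scaled by each library's total over these loops, with no pseudocount. Intervals are 95% exact conditional binomial intervals of a ratio of 2 counts and exact (Clopper-Pearson) binomial intervals of a share. They cover counting error only, because each group has 1 library. They may be too narrow even for that, because reads without molecular identifiers are not independent molecules. No p-value was computed, since loops and genes are not replicates. Chromosomes 1 to 22 and X were used.

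Genes came from a RefSeq table of the assembly GRCh38.p14, the same build as hg38, with 19974 protein-coding genes. A loop counted for a gene when an anchor overlapped the gene body. The design fixed before the data were examined used a window around the transcription start, which could not be made because the table gives no strand. The gene body became the main assignment in its place. All 271 genes of the lists fixed by name were found in the table. A search of anchors for CTCF motifs was planned and not run, as no genome sequence was used here. The named genes are the 10 highest and 10 lowest in APH vs DMSO and in HU vs H2O among genes with at least 100 counts in the 2 libraries together, whose interval excludes a ratio of 1 and whose log2 ratio is larger in size than that of H2O vs DMSO. Genes with the same loops count as 1 place, and 1 place that the rule names is left out of the text and the plot of named genes. The rule also names the members of each list with the highest and lowest ratio, the 3 loops with most counts per library and the single loops with the highest and lowest ratio. Members of the lists have no minimum of counts.

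The 12 gene lists were common fragile site genes, B cell identity, NF-kB and Epstein-Barr virus latency responsive genes, p53 and DNA damage response targets, DNA replication and its checkpoint, cohesin with its regulators and CTCF, replication-dependent histone genes, T cell genes, myeloid and erythroid genes, HOX clusters, ribosomal protein genes and long genes of at least 500 kb. The median log2 ratio of each list was placed among 10000 random lists of the same size matched on mean count, as a description of these libraries. Lists with fewer than 3 measured genes have no percentile.

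The steps were tested on simulated data drawn from the real counts of 4831 genes. Of genes changed 2-fold, 100% were recovered for APH vs DMSO and 99.4% for HU vs H2O. Of genes changed 1.5-fold, 85.7% and 74.7% were recovered. Of unchanged genes, 3.78% to 5.26% fell outside the interval, and 6 of 100 random lists fell outside the central 95% for APH vs DMSO. A second simulation drew 100 sets of counts with no difference between libraries.

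Alternatives covered the scaling, the choice of vehicle, stricter counts of at least 24, thinning of counts, tolerance of 1 or 2 bins in matching anchors, loops listed in both libraries of a contrast, ratios relative to loops of the same span class, division by the expected count, and the assignment of loops to gene ends within 5 kb.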

Results

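Chromatin loops bound by SMC1, a subunit of the cohesin ring, were mapped by HiChIP, which joins proximity ligation of chromatin with immunoprecipitation. The cells were GM12878, an Epstein-Barr virus transformed B lymphoblastoid line. One culture was labelled as treated for 18 h with 0.4 µM aphidicolin (APH), an inhibitor of replicative DNA polymerases. Another was labelled as treated for 18 h with 0.2 mM hydroxyurea (HU), which blocks ribonucleotide reductase and so lowers the supply of deoxynucleotides. Dimethyl sulfoxide (DMSO) was the vehicle of aphidicolin and water (H2O) that of hydroxyurea. Each of the 4 groups holds 1 library. No difference below therefore has a replicate check, and each compares libraries, not conditions. The difference between the H2O and DMSO libraries, neither of which received a drug, is given as the reference for how far libraries differ. The question the design poses is how slowed DNA replication affects cohesin loops.

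The deposited lists hold called loops between bins of 5 kb, with the contact count of each. The DMSO library lists 17660 loops with 449565 contact counts, the APH library 27395 loops with 732695, the H2O library 22446 loops with 575756, and the HU library 21448 loops with 550828. The median listed loop had 20 counts in every library. The most heavily counted loops were the same places in several libraries. A loop of 25 kb on chromosome 15 between COXFA4L3 and SLC30A4-AS1 had 204 counts in DMSO, 388 in APH, 258 in H2O and 322 in HU. A loop of 60 kb on chromosome 19 between KISS1R, which encodes the kisspeptin receptor, and WDR18 had 238, 282, 215 and 225 counts in the same order. Loops of 55 kb and 95 kb on chromosome 1, whose anchors lie on no protein-coding gene, were among the 3 with most counts in each library, at 271 and 225 counts in DMSO. Every interval below covers counting error only, since each group has 1 library. All counts come from PCR reads with no molecular identifiers stated, so the intervals may be too narrow.

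Listed loops were shorter in both drug libraries than in both vehicle libraries. Loops under 100 kb made up 51.3% of the APH list (95% exact binomial interval 50.7 to 51.9) and 45.3% of the DMSO list (44.6 to 46.0). They made up 51.6% of the HU list (50.9 to 52.2) and 45.6% of the H2O list (45.0 to 46.3). As deposited, the intervals of the DMSO and H2O lists overlapped, and neither reached those of the drug lists. With at least 24 counts HU stood 3.78 points above H2O and H2O 2.84 above DMSO, and with counts thinned to the lowest list total these were 4.91 and 5.32, so that the difference between the vehicles was then the larger. With counts thinned to the lowest total over loops listed in all 4 libraries they were 5.68 and 2.04. At the other end, loops of 500 kb or more were 2.07% of the APH list against 2.96% in DMSO, and 2.28% of the HU list against 2.86% in H2O. The median span was 95 kb in APH and in HU, 110 kb in DMSO and 105 kb in H2O. The ratio of listed loops was 1.55 for APH over DMSO, with 1.43 times the length of anchors and 1.05 times the mean count per loop, while HU over H2O gave 0.956, with 0.992 times the length of anchors and nearly the same mean count. A list depends on depth and on the caller's threshold, and with counts thinned at random to the lowest list total, these ratios of loops went to 0.885 and 1.01, and H2O over DMSO from 1.27 to 0.975.

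**Figure D1:**
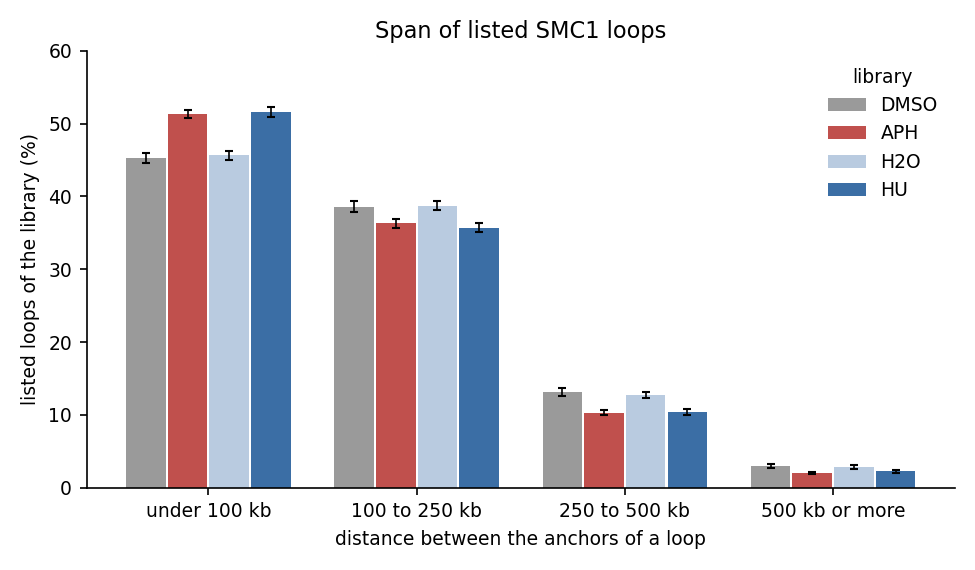
Share of the listed SMC1 loops of each library (vertical axis, percent) in 4 classes of distance between anchors (horizontal axis), with 1 library per bar and exact binomial 95% intervals as error bars. The APH and HU bars stand at 51.3% and 51.6% under 100 kb, above DMSO at 45.3% and H2O at 45.6%, and below them in the longer classes.

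The lists of the drug libraries also shared more with each other than HU shared with its vehicle. Of the HU loops, 70.8% (70.2 to 71.4) were listed in APH with the same pair of bins, and 61.3% (60.6 to 61.9) were listed in H2O. Of the DMSO loops, 75.3% (74.7 to 76.0) were listed in APH and 70.6% (69.9 to 71.3) in H2O, where the APH list is the longest. With equal numbers of loops per library the order turned, to 62.0% of DMSO loops in APH and 63.2% in H2O, while HU loops were at 65.3% in APH and 61.3% in H2O. In total 9529 loops were listed in all 4 libraries, out of 41846 listed in any. Loops listed in both drug libraries and in neither vehicle numbered 2380, with a median span of 75 kb. Loops listed in both vehicles and in neither drug library numbered 849, with a median span of 135 kb. Among the first kind, NR6A1, which encodes a nuclear receptor, carried 8 loops, and PDE4D, a cyclic AMP phosphodiesterase gene, and REEP1 carried 5 each. Among the second kind, RAPGEF1 carried 4 loops, and the genes with 3 included MYB, a transcription factor gene of blood progenitors, CASP10, an initiator caspase gene, PICALM and MLLT3. These genes were picked by their number of loops after the lists were seen, and an unlisted pair of bins is not a measured 0. Pairs of a drug and a vehicle library held loops of their own as well. Loops listed only in APH and H2O numbered 1990, only in DMSO and APH 1080, only in H2O and HU 942, and only in DMSO and HU 545.

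Contact counts of the 9529 loops listed in all 4 libraries were compared next, each library scaled by its total over these loops. In the APH library short loops stood higher and long loops lower than in DMSO. Pooled counts of loops under 100 kb had a log2 ratio of 0.08 (0.07 to 0.09), those of 100 to 250 kb -0.04 (-0.05 to -0.03), those of 250 to 500 kb -0.18 (-0.20 to -0.15), and those of 500 kb or more -0.24 (-0.29 to -0.19). The HU library differed from H2O in the same way, at 0.08 (0.07 to 0.09), -0.06 (-0.07 to -0.05), -0.13 (-0.15 to -0.11) and -0.16 (-0.22 to -0.11). Between the vehicles all 4 intervals included 0, with values from -0.01 to 0.01. The median of long loops (500 kb or more) minus that of short loops (under 100 kb) was -0.29 for APH vs DMSO and -0.23 for HU vs H2O on the log2 scale. It was -0.02 for H2O vs DMSO, and counts drawn with no difference between libraries gave -0.11 to 0.06 for APH vs DMSO and -0.09 to 0.10 for HU vs H2O. After division by the deposited expected counts, the value was -0.085 for APH vs DMSO, -0.27 for HU vs H2O, -0.22 for APH vs H2O, -0.13 for HU vs DMSO and 0.15 for the vehicles.

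**Figure D2:**
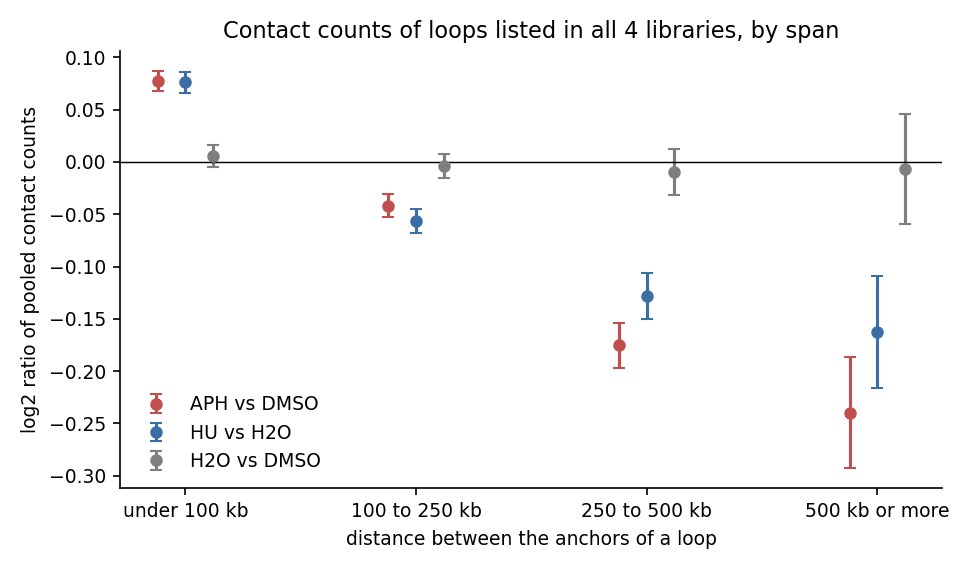
Log2 ratio of the pooled contact counts (vertical axis) of loops listed in all 4 libraries, each library scaled by its total over these loops, by distance between anchors (horizontal axis), for APH vs DMSO, HU vs H2O and H2O vs DMSO, with exact conditional binomial 95% intervals that cover counting error only. Both drug contrasts go from 0.08 under 100 kb to -0.24 (APH) and -0.16 (HU) at 500 kb or more, and the vehicle contrast stays within -0.01 to 0.01.

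More single loops differed in both drug contrasts than in counts drawn with no difference, though they were a small share. In APH vs DMSO the interval of the ratio excluded 1 for 263 loops that were higher and 261 that were lower, together 5.50% of 9529. In HU vs H2O these were 374 and 329, together 7.38%, and in H2O vs DMSO 120 and 130, together 2.62%. Counts drawn with no difference gave a median of 3.25%, 3.17% and 3.03% in the same order. The draws ranged from 2.83% to 3.66%, 2.72% to 3.75% and 2.64% to 3.54%, so the vehicle value lay just below its range. By the rule for single loops, the highest in APH vs DMSO was a loop of 25 kb on chromosome 19 (46515001 to 46545000, build hg38) with a log2 ratio of 1.15 (0.49 to 1.84). The lowest was a loop of 235 kb on chromosome 3 with an anchor at BOC and CFAP44, at -1.10 (-1.69 to -0.52). In HU vs H2O the highest was a loop of 45 kb on chromosome 1 with an anchor at the collagen gene COL16A1, at 1.65 (1.01 to 2.34), where H2O itself stood at -0.82 against DMSO. The lowest was a loop of 235 kb on chromosome 12 that joins NINJ2 to the kinase gene WNK1, at -1.14 (-1.80 to -0.51). All these directions are relative to the loops listed in all 4 libraries. Scaling by all listed loops instead moved every ratio by -0.38 in APH vs DMSO, 0.05 in HU vs H2O and -0.24 in H2O vs DMSO, so that 1.30%, 64.7% and 1.25% of the differing loops were higher, in place of 50.2%, 53.2% and 48.0%.

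APH was then compared with DMSO gene by gene, with the counts of all shared loops that have an anchor on the gene summed. LRRC28, a leucine-rich repeat gene on chromosome 15 (99251481 to 99390729), was lowest, with 39 counts in APH against 74 in DMSO and a log2 ratio of -1.25 (-1.85 to -0.67). CD274, which encodes the immune checkpoint ligand PD-L1, stood at -0.82 (-1.42 to -0.22). Lower as well were TLK1, a kinase of chromatin assembly (-1.02), PACC1 (-0.92), the transcription factor gene ZFHX3 (-0.89), GGA1 (-0.87), SAE1, a subunit of the SUMO-activating enzyme (-0.82), TSTD2 (-0.81), OSR2 with LOC112268016 (-0.80), and CHTF18, a clamp loader subunit that acts in sister chromatid cohesion, with RPUSD1 (-0.78). Higher in APH was KCNH2, which encodes a cardiac potassium channel (0.81, 0.29 to 1.34). The neighbouring calcium-binding protein genes S100A14 (0.81) and S100A13 (0.76) were higher, as were LRRC74A (0.82), PTPN5 (0.81), the kinesin gene KIF19 (0.80), ACP3 (0.76), ANAPC16 with ASCC1 (0.74) and FAM13B (0.74). By the same rule 111 genes were higher and 122 lower of 2520 with at least 100 counts. The interval excluded 1 for 9.92% of genes in APH vs DMSO and 4.69% of 2387 genes in H2O vs DMSO. Against H2O in place of DMSO, the interval still excluded 1 in the same direction for 7 of the 10 places named as higher but for only 3 of the 10 named as lower, LRRC28, CD274 and TSTD2. ANAPC16 with ASCC1 went to 0.03, TLK1 to -0.45 and ZFHX3 to -0.18, and with loops assigned to gene ends PTPN5 went to 0.0092 and TSTD2 to -0.11.

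Among genes with at least 100 counts, HU stood highest against H2O at SLC5A1, which encodes an intestinal sodium-glucose cotransporter, on chromosome 22 (32043261 to 32113029), with 79 counts in HU against 32 in H2O and a log2 ratio of 1.32 (0.71 to 1.96). PYY, a gut peptide hormone gene (1.25), the smooth muscle gene LMOD1 (1.06), PIGR, the polymeric immunoglobulin receptor gene (1.04), IP6K3, an inositol phosphate kinase gene (0.99), and ACOT13 (0.99) followed. ADAM15 with EFNA4 (0.92), C8orf76 with TBC1D31 (0.91), PLA2G4D (0.90) and UQCC2 (0.89) completed the higher side. LRRC28 was again lowest, at -1.13 (-1.78 to -0.51). CFLAR, which encodes an inhibitor of caspase 8 activation, stood at -0.89 (-1.43 to -0.37), and MRTFA, a coactivator of serum response factor with 7 loops, at -0.74 (-1.05 to -0.44). PTMA (-0.90), SNX25 (-0.85), EPB41L4A (-0.84), the kinase gene CAMK1D (-0.76), PIK3R5 with PIK3R6, regulatory subunits of a phosphoinositide 3-kinase (-0.75), RNF19B (-0.72) and HS2ST1 (-0.71) were lower too. By the rule 201 genes were higher and 195 lower of 2452, and the interval excluded 1 for 16.5%. These are more genes than in APH vs DMSO, but with the vehicles exchanged the rule took 308 genes for HU vs DMSO and 310 for APH vs H2O. Against DMSO in place of H2O, the interval excluded 1 in the same direction for 8 of the 10 places named as higher and 5 of the 10 named as lower. H2O itself stood apart from DMSO at SLC5A1 (-0.76), PYY (-0.62), ADAM15 with EFNA4 (-0.55) and PIK3R5 with PIK3R6 (0.53), and against DMSO these went to 0.56, 0.63, 0.37 and -0.22 in HU, the last 2 places with intervals that included 1. CFLAR went to -0.49 (-1.07 to 0.07) against DMSO, and with loops assigned to gene ends CFLAR went to -0.13 and PTMA to -0.11.

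**Figure D3:**
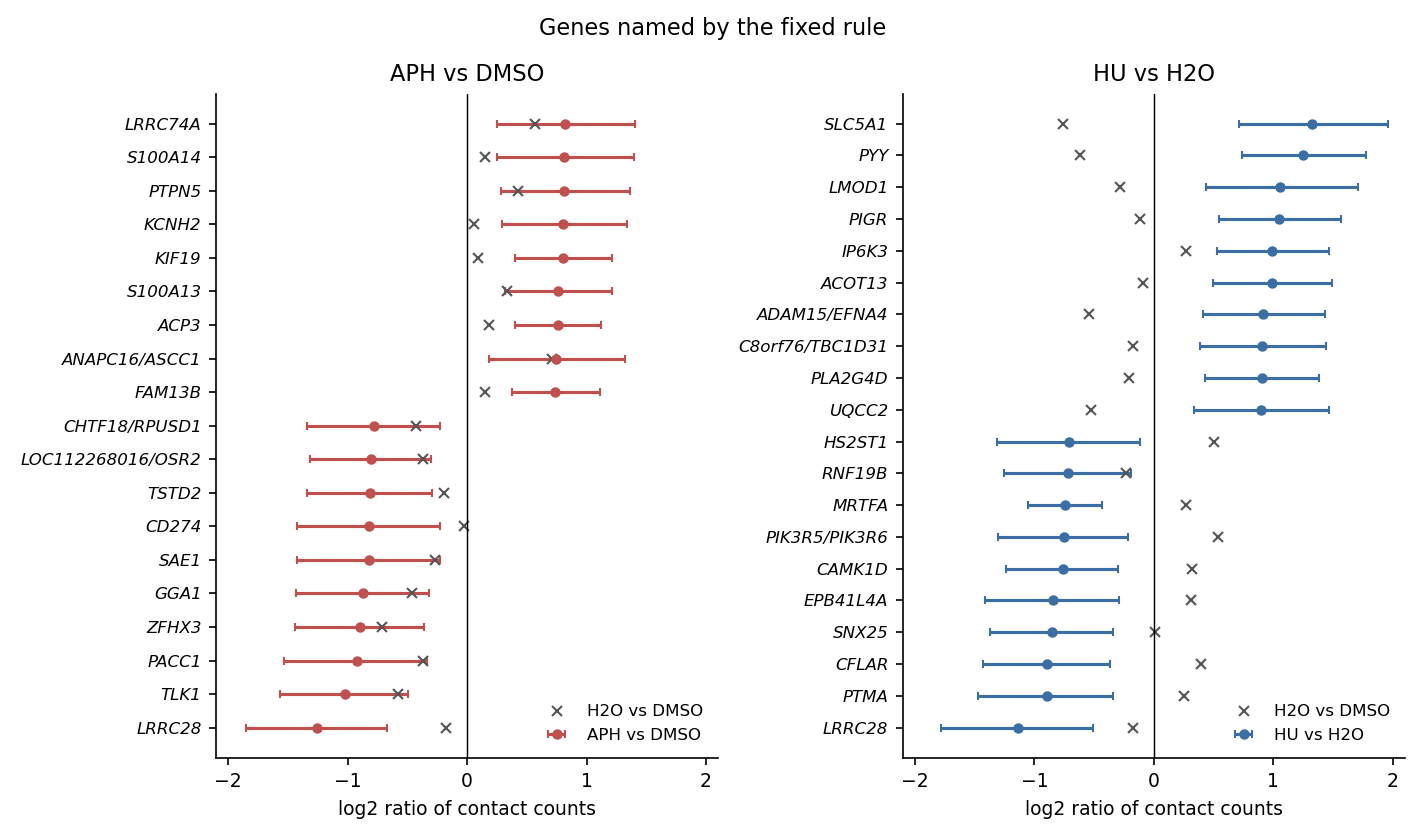
Log2 ratio of contact counts (horizontal axis) at the 10 highest and 10 lowest places by the fixed rule, with 1 place not drawn, for APH vs DMSO (left) and HU vs H2O (right), as points with exact conditional binomial 95% intervals that cover counting error only, and H2O vs DMSO for the same genes as crosses. LRRC28 is lowest in both panels, at -1.25 and -1.13, and for ANAPC16 with ASCC1 the cross at 0.71 lies close to the point at 0.74.

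Both drug libraries differed from their own vehicles at many of the same genes. The contrasts APH vs DMSO and HU vs H2O share no library. Of 2174 places with enough counts in both (genes with the same loops taken as 1 place), 43 were higher in both with intervals that excluded 1, where independent lists would share 9.77. A further 32 were lower in both, where independent lists would share 10.2. Only LRP5, a Wnt coreceptor gene, and BCR went opposite ways, LRP5 at -0.39 with APH and 0.32 with HU, and BCR at 0.44 and -0.43, where independent lists would give 19.9 such places. H2O stood apart from DMSO at both genes, with LRP5 at -0.39 and BCR at 0.43. With the vehicles exchanged, 75 places again went the same way, and CSK and SLC8A2 went opposite ways. In the remaining pairing of the libraries, APH vs HU with DMSO vs H2O, CCDC124, SLC8A2 and SBF2 went the same way where independent lists would give 3.16 places, and BCR, CDK18, LRP5 and BPIFB4 went opposite ways where they would give 2.99. This count and these genes were chosen after the values were seen, and overlapping genes share some loops. Both contrasts had short loops higher and long loops lower, which independent lists leave out. The overlap was not computed relative to span class. The named places had a median span of 50 kb where higher and 176 kb where lower with APH, and 61 and 135 kb with HU. Across the 9529 loops the log2 ratios of APH vs DMSO and HU vs H2O had a Pearson r of 0.226 and a Spearman rho of 0.221, over loops, which are not independent replicates. Simulated counts with no difference gave r from -0.04 to 0.03, and the remaining pairing gave -0.0028.

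Genes lower in both drug libraries, named here after their values were seen, included CCR7, the chemokine receptor of lymph node homing (-0.28 with APH, -0.29 with HU), RHOH, a lymphoid GTPase gene (-0.27, -0.35), STIM1, the calcium sensor of store-operated entry (-0.50, -0.58), GRB2, an adaptor of receptor signalling (-0.41, -0.44), MEF2A (-0.45, -0.63), CAMK1D (-0.61, -0.76) and RGL1 (-0.59, -0.57). Genes higher in both, picked in the same way, included IP6K3 (0.73, 0.99), KCNH2 (0.81, 0.64), SLC5A1 (0.52, 1.32), SLC2A4, the insulin-responsive glucose transporter gene (0.61, 0.86), FGF1 (0.66, 0.75), NECTIN4 (0.70, 0.72), CASQ2, a calcium store protein gene of heart muscle (0.38, 0.60), and the tetraspanin gene TSPAN15 with 7 loops (0.54, 0.70). No theme was tested for enrichment among these places.

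**Figure D4:**
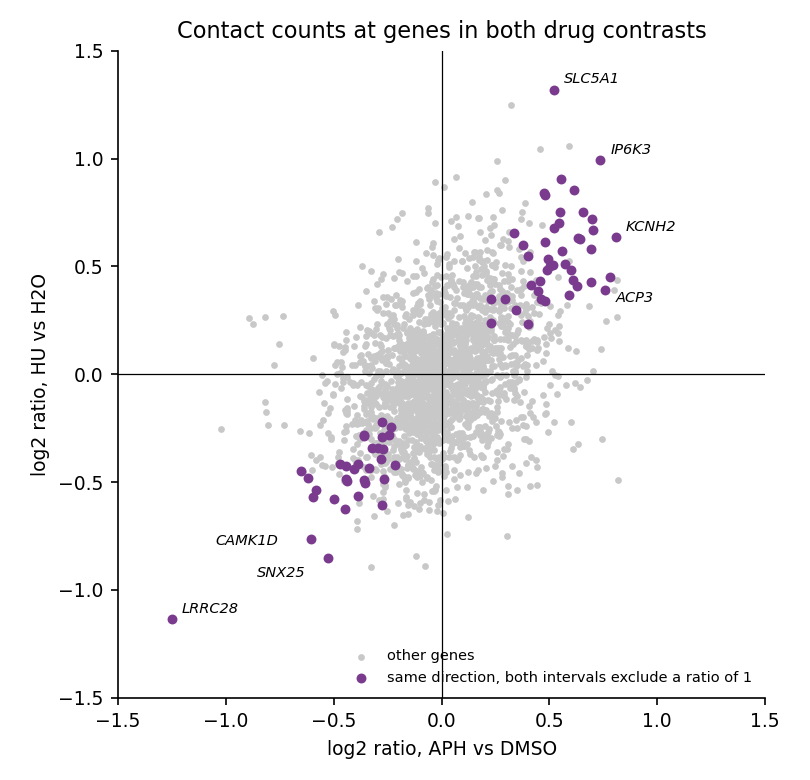
Log2 ratio of contact counts at 2174 places, APH vs DMSO on the horizontal and HU vs H2O on the vertical axis, 1 point per gene or per set of genes with the same loops. The 75 places whose intervals exclude a ratio of 1 in the same direction in both contrasts are drawn in purple, 43 at the upper right and 32 at the lower left.

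Of the 12 gene lists as fixed, only the HOX clusters lay outside the central 95% of random lists in HU vs H2O. In simulated data 6 of 100 random lists also fell outside, so such a list among those placed in both drug contrasts can arise at random. The median log2 ratio of 11 measured HOX genes was -0.27, at percentile 1.04 among 10000 random lists of the same size and similar counts. HOXB3, in the developmental HOXB cluster, was lower (-0.39, -0.73 to -0.06), and the intervals of the other 10 included 1, from HOXB5 (-0.42) to HOXD8 (0.96). HOXC4, HOXC5 and HOXC6 have the same 4 loops (-0.33), and HOXD12 and HOXD13 have the same counts over 2 loops. The list thus holds fewer independent values than genes. Random lists drew genes independently, so the percentile may be too extreme. Between the vehicles the list of common fragile site genes stood at percentile 99.1. With loops assigned to gene ends the HU median of the HOX genes was -0.15, at percentile 5.49. In APH vs DMSO the HOX median was -0.06, at percentile 32.8, with HOXB5 lowest (-0.67, -1.36 to 0.02). No list passed the central 95% of random lists in APH vs DMSO.

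Genes that answer NF-kB and Epstein-Barr virus latency proteins came closest with APH, with a median of -0.18 over 8 measured genes at percentile 3.67. CCR7 (-0.28, -0.51 to -0.04) and the apoptosis inhibitor gene BCL2 (-0.37, -0.68 to -0.06) were lower, and the intervals of the other 6 included 1, from RELB (-0.60) to ICAM1 (0.26). In 3 of the 4 alternatives this list lay below the central 95% with APH, while against H2O it stood at percentile 16.6. In HU vs H2O this list stood at -0.16 and percentile 12.3, with CCR7 (-0.29) lower, and CFLAR (-0.89) lower against H2O but not with an interval that excluded 1 against DMSO. Against DMSO the HU median of the list went to -0.30, at percentile 0.75, while with gene ends it lay within the central 95%. The 16 measured genes of B cell identity stood at -0.04 with APH, at percentile 40.5, and at -0.10 with HU, at percentile 17.7. Of these, IKZF3 (-0.35) and RUNX3 (-0.25), transcription factor genes of lymphocytes, were lower with APH, and none had an interval that excluded 1 with HU, from CD79A (-0.57) to IRF8 (0.26). Genes of T cells stood at 0.13 with APH and -0.19 with HU, at percentiles 91.1 and 9.49, with CD247 lower in APH (-0.85) and CD4 highest in both (0.26 and 0.21, intervals that included 1). Against H2O the APH median of the T cell genes turned to -0.03. Of the myeloid and erythroid genes only CEBPB and KLF1 were measured, with medians of -0.28 with APH and 0.38 with HU, and KLF1 higher in HU (0.94, 0.10 to 1.82). KLF1 rests on 1 loop with 36 counts in HU and 19 in H2O, and H2O itself stood at -0.73 against DMSO.

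Genes of the response to DNA damage and of replication itself showed a mixed picture. Targets of p53 stood at -0.20 in HU vs H2O, at percentile 6.72, over 8 measured genes. CDKN1A, the p21 gene on chromosome 6 (36676463 to 36687332), had 200 counts in HU against 313 in H2O (-0.63, -0.89 to -0.37), and ZMAT3 was lower too (-0.83, -1.48 to -0.20). With APH this list stood at -0.05, at percentile 38.6, with no interval that excluded 1, from PPM1D (-0.81) to FAS (0.63). The HU median of the p53 targets went to -0.38 against DMSO and to 0.07 when loops were assigned to gene ends in place of gene bodies. The APH median of the p53 targets went to -0.23 against H2O, so its distance from the HU value depends on the vehicle. Genes of DNA replication and its checkpoint stood at 0.03 with APH and -0.07 with HU over 10 genes, at percentiles 56.5 and 26.1, with MCM10 lowest in both (-0.54 and -0.31). Genes of cohesin, its regulators and CTCF stood at -0.12 and 0.02 over 8 genes, at percentiles 19.4 and 55.1, with SMC3 highest with APH (0.67) and lowest with HU (-0.68). No interval excluded 1 in these last lists in either drug contrast. The only measured replication-dependent histone gene was H4C3, at -0.12 with APH and -1.02 (-1.87 to -0.22) with HU. H4C3 rests on 1 loop with 20 counts in HU and 41 in H2O, and H2O itself stood at 0.54 against DMSO.

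Common fragile site genes, which break under low doses of aphidicolin, did not shift as a group against the own vehicle of each drug. Over 12 measured genes the median was -0.01 with APH and -0.04 with HU, at percentiles 50.4 and 38.7, while H2O vs DMSO stood at 0.21 and percentile 99.1. Against the other vehicle the medians went to -0.16 for APH and 0.12 for HU. Of these, AUTS2 was higher (0.53) and RORA lower (-0.98) in HU, and the deletion-prone genes FHIT (-0.48 and 0.13) and WWOX (0.34 and 0.28) had intervals that included 1. Long genes of at least 500 kb stood at -0.03 in both contrasts over 129 genes, at percentiles 44.8 and 34.2, with PSD3 highest (1.04, 0.21 to 1.95) and VPS13B lowest (-0.99, -1.61 to -0.38) with APH, and NALF1 (0.90) and HDAC9 (-0.98), whose intervals included 1, with HU. Among them 6 were higher and 7 lower with APH, and 7 higher and 6 lower with HU. The ribosomal protein list stood at 0.09 with APH and -0.13 with HU over 21 genes, at percentiles 86.0 and 9.69. Its fixed symbol rule also took kinase genes such as RPS6KA1 and RPS6KA5, and the 12 measured genes left without such symbols stood at 0.03 and -0.25, at percentiles 64.4 and 2.03, so that this restricted list, formed after the data were seen, lay outside the central 95% with HU. Among these RPL26 was lower with APH (-1.06, -2.09 to -0.09), and with HU RPL11 was lower (-0.83) and RPL38 higher (1.34, 0.47 to 2.27). RPL11 and RPL38 rest on 1 loop each, and H2O itself stood at 0.59 and -0.51 against DMSO there.

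Whole chromosomes differed little. In APH vs DMSO the interval excluded 1 for chromosome 2 (-0.04) and chromosome 11 (0.03) of 23. In HU vs H2O it did so for chromosome 21 (-0.15, -0.24 to -0.07), 6 (-0.07), 8 (-0.05), 2 (-0.05), 19 (0.06) and 11 (0.08). Between the vehicles it did so for 3 chromosomes, 4 at 0.07 (0.03 to 0.11), 19 at -0.04 (-0.07 to -0.02) and 21 at 0.12 (0.03 to 0.20). The APH values are thus no larger than differences between libraries that received no drug, and the HU values of chromosomes 19 and 21 go opposite to those of the H2O library they are set against. Both anchors lay on protein-coding gene bodies for 40.2% of APH loops (39.6 to 40.8), 39.4% of DMSO loops (38.6 to 40.1), 39.8% of HU loops (39.2 to 40.5) and 40.7% of H2O loops (40.1 to 41.3). These shares differed between APH and DMSO, and between HU and H2O, by less than between the vehicles.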

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

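Choices were fixed before the data were examined, except thinning for loop span and to the totals over shared loops, observed over expected counts, gene ends, the restricted ribosomal list and the correlation relative to span class, which were tests chosen after the data were seen. No paired analysis was possible because each group has 1 library, and no library could be left out. Windows at transcription starts, a start inside an anchor and both CTCF alternatives were not run, since strand and sequence were lacking. The gene body took the place of the fixed window as the main assignment. Of the alternative values that answer comparisons, 63 stayed within counting error or 1.5 times, 59 moved and 3 turned around. Of the others, 225 stayed and 25 moved. Of the named genes, 8 moved against the other vehicle and 38 did not, and all 46 stayed with loops listed in both libraries. With gene ends 4 moved and 28 did not, and the rest had no shared loop near a gene end and could not be checked. Relative to span class all 46 stayed, but none could have moved. The class medians reached at most 0.23 in size, less than the half-width of every named gene's interval. The passing genes shared with the other vehicle numbered 115 of 233 for APH and 184 of 396 for HU. Those that also passed relative to span class numbered 151 of 233 for APH and 293 of 396 for HU. Where no cause is given, the cause was not tested.

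Thinned to the lowest library total, the ratio of loop numbers turned to 0.885 for APH vs DMSO, 1.01 for HU vs H2O and 0.975 for H2O vs DMSO. List totals move with the number of loops called, so this removes more counts from longer lists, and thinning to the lowest total over shared loops gave 1.24 for APH vs DMSO. The difference in the percent of loops under 100 kb moved to 7.50 for APH and 10.8 for HU among loops not listed in all 4 libraries. With at least 24 counts it was 3.78 for HU and 2.84 for the vehicles. Thinned to the lowest library total it was 13.4 for APH, 4.91 for HU and 5.32 for the vehicles. Thinned to the total over shared loops it was 9.76 for APH and 2.04 for the vehicles.

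With anchors within 1 bin, within 2 bins and with at least 24 counts, DMSO loops listed in APH went to 87.7%, 89.7% and 84.2%, HU loops in H2O to 76.2%, 79.3% and 67.4%, DMSO loops in H2O to 84.3%, 86.6% and 78.1%, and HU loops in APH to 84.0%, 86.7% and 79.2%. With equal numbers of loops these were 62.0% for DMSO in APH, 63.2% for DMSO in H2O and 65.3% for HU in APH.

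Scaled by all listed loops, the percent of loops higher and lower was 0.220 and 16.7 for APH vs DMSO, 4.83 and 2.63 for HU vs H2O, and 0.0840 and 6.63 for H2O vs DMSO, by the shift that this scaling gives to every loop. By the median ratio, 3.11 were higher for APH. With loops listed in both libraries the values were 2.32 and 2.02 for APH, 3.04 and 2.69 for HU, and 1.03 and 1.07 for the vehicles. Against the other vehicle 3.42 were higher and 3.36 lower for APH, and 2.95 lower for HU. Long minus short loops gave -0.085 for APH vs DMSO, -0.22 for APH vs H2O, -0.13 for HU vs DMSO and 0.15 for H2O vs DMSO on the observed over expected scale, and -0.14 for HU vs H2O with loops listed in both libraries.

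Gene lists outside the central 95% of random lists numbered 2 for APH with gene ends (NF-kB, and myeloid and erythroid genes), 1 relative to span class and 1 with loops listed in both libraries (NF-kB in each). For HU they were 0 with gene ends and 3 against the other vehicle (NF-kB, p53 targets and HOX). The correlation of APH and HU ratios was 0.314 with at least 24 counts in every library and 0.195 relative to span class. Over all listed loops chromosome 6 stood at -0.13, 8 at -0.10, 11 at 0.17, 19 at 0.13 and 21 at -0.27 in HU vs H2O. Relative to span class chromosome 19 stood at 0.031 in HU vs H2O and chromosome 2 at -0.0068 in APH vs DMSO.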

Other observations

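All tests in this part were chosen after the results they bear on were seen. Regions of 2 Mb differed between libraries as well as single genes. Of 298 windows with at least 1500 counts, the interval excluded a ratio of 1 for 83 in HU vs H2O, 47 in APH vs DMSO and 13 in H2O vs DMSO. The lowest in HU was on chromosome 8 (126000001 to 128000000), at -0.56 (-0.74 to -0.39), with APH at -0.18, where no anchor of a shared loop lay on a protein-coding gene. A window of chromosome 6 with the Src family kinase gene FYN stood at -0.52 (-0.72 to -0.31) in HU and -0.17 (-0.36 to 0.03) in APH.

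Lower in both drug libraries were 10 windows and higher in both 12, and none went opposite ways. The lower ones included chromosome 13 around RB1, the retinoblastoma tumour suppressor gene (-0.27 in both), chromosome 2 around PELI1 (-0.22 with APH, -0.25 with HU) and chromosome 10 around CAMK1D (-0.25, -0.20). The higher ones included chromosome 10 around TSPAN15 and the proteoglycan gene SRGN (0.34, 0.33), chromosome 1 around the S100 genes and IVL of the epidermis (0.19, 0.39), and chromosome 1 around the interferon-inducible DNA sensor genes AIM2 and IFI16 (0.22, 0.21). Across the 298 windows APH and HU ratios had a Pearson r of 0.630 and a Spearman rho of 0.646, and r was 0.548 relative to loops of the same span. The remaining pairing, APH vs HU with DMSO vs H2O, gave 0.0098. Windows are not independent replicates.

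As deposited, listed loops were shorter in both drug libraries. The length of the list is argued against as the whole cause for HU, since the HU and H2O lists are of similar length and the share under 100 kb still differed by 5.92 points. That is the difference that made the pattern, and lists of similar length need not have the same depth, which is unknown. With counts thinned to the lowest list total the vehicles differed by more than HU and H2O, though not with counts thinned to the lowest total over shared loops. Depth therefore stays open. A stronger background of short-range contacts in the drug libraries stays open. On the observed over expected scale long minus short loops gave -0.085 for APH vs DMSO, smaller in size than the vehicles' 0.15, although HU vs H2O gave -0.27. An effect of slowed replication on the reach of cohesin may also account for it, which was not tested, because each group has 1 library and the labels give no batch.

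The ratios of APH and HU went together across loops. Loop span between the 4 span classes is argued against as the whole cause, since r was 0.195 after each class was centred. Span differences within a class were not removed, so span on a finer scale stays open. The choice of loops listed in all 4 libraries is argued against, since the remaining pairing of the libraries gave -0.0028. More copies of early replicating DNA under slowed replication stay open. Centring on gene density as a stand-in within span classes left r at 0.195, so that it moved nothing. A first form of this test, the highest minus the lowest density class, went both ways, with 0.09 for APH and 0.12 for HU over all loops, -0.0078 and 0.11 under 100 kb, -0.0011 and 0.0085 at 100 to 250 kb, 0.04 and -0.03 at 250 to 500 kb, and -0.24 and -1.25 at 500 kb or more. In that last class, which holds 240 loops over all densities, the vehicles gave 0.89. The HU value of -1.25 is thus set against an H2O library that itself stood apart from DMSO. How many of the 240 loops lie in the highest density class was not given, so both values may rest on few loops. A shared response to the drugs, or handling shared by the drug libraries, may account for the rest of the agreement, which was not tested.

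Loops with anchors that carry many other loops were lower in both drug libraries than loops with sparse anchors. Regression to the mean from counting noise in the ratio's own vehicle is argued against. With anchors counted in the other vehicle the difference was still -0.13 for APH and -0.21 for HU. Anchors were not counted in a drug library for these contrasts, so a choice of loops that stand high in both vehicles stays open. The value between the vehicles, -0.02, came from anchors counted in HU and is not a like reference. Loop span between classes is argued against, since the difference was -0.13 for APH and -0.25 for HU within 100 to 250 kb. Span differences within that class were not removed. Background at the anchors stays open, since the observed over expected scale gave -0.089 for APH and -0.12 for HU. Weaker loop clusters under slowed replication may be a candidate explanation, which the design with 1 library per group leaves untested.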
